A study of Danio rerio with 8 samples.

How the data were processed

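Gene expression was measured in whole zebrafish embryos at 6 hpf on 8 Affymetrix zebrafish genome arrays. Groups were taken from the sample titles, which call the 3 control and the 3 severe arrays biological replicates. The titles do not say whether these came from separate clutches. P-values measure the spread between these samples.

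The deposited table holds log2 values, 1 per probe set and array. MAS5 was named per the submitters' processing notes, with no version given. MAS5 combines the probes of a probe set into 1 signal after subtracting mismatch signal, which leaves dim probe sets noisy. The values themselves show that each array had been scaled to a mean linear signal of 500 after trimming 2% of probe sets at each end. Values at the lower end stop at 0, where between 40 and 128 probe sets per array lay. No detection calls were used here. A plan written before the data were examined allowed for linear values with a pseudocount. As the table proved to be on the log2 scale, it was used as deposited, as that plan provided.

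Gene names came from the platform annotation, with symbols updated through Entrez numbers for 10711 probe sets. Of 15502 probe sets other than controls, 10795 had 1 symbol, 135 had several and 4572 had none. No gene was named from a probe set with several symbols. A gene with several probe sets was represented by the one with the highest mean. No genome was used here, so no coordinates are given.

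The 115 AFFX control probe sets were left out of tests. Probe sets with a mean over all 8 arrays at or above the 40th percentile (log2 5.585) were kept, which left 9301 probe sets and 6192 genes. Group means were fitted with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. There were 22 lists fixed before the data were examined. The hox list had 1 tested gene and no set test, so the other 21 were adjusted together in each comparison. They cover arginine methyltransferases, p53 and DNA damage, gadd45, apoptosis, MAP kinase and AP-1, chaperones and the unfolded protein response, innate immunity, maternal transcripts, early zygotic genes, mesendoderm, dorsal organizer, BMP, Wnt and movements, neural plate, hox, cell cycle, ribosomal proteins, enveloping layer, yolk syncytial layer, germ cells, blood and muscle.

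The position of a single array between control and severe used 200 probe sets per direction, chosen without 1 control and 1 severe array and measured on those held out. Background was the 95th percentile of 17 negative control (Tag) probe sets, log2 5.10. This bound was chosen after the data were seen. A gene under it on every array of the dimmer group is given as "at least N-fold", the bright mean against that bound.

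Named genes followed a rule fixed before the data were examined. It took prmt6 and gadd45aa, the 12 largest rises and falls in severe embryos with no overlap of arrays, the 5 largest in mild and normal embryos, and up to 4 genes with the smallest p per list. Clone-style symbols were left out. Figures were drawn with matplotlib 3.10.9.

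The steps were tested on simulated data. For severe against control, 10% of 1.5-fold, 48% of 2-fold, 90% of 4-fold and 94% of 8-fold changes were recovered among 9301 probe sets (50 of each size), and 5 of 126 calls were wrong. For the single mild array, 0 of 50 changes of 2-fold and 18% of 2.83-fold changes were recovered. Simulated arrays placed midway and at the control level came out at 0.519 and -0.012. Camera found the shifted set and called 0 of 20 unchanged ones. Simulated genes varied independently, so this does not test the preset correlation on lists whose members vary together. Far fewer probe sets were changed than were called in the data, so recovery there may differ.

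Alternatives covered the pseudocount, quantile normalization, median centring, the filter on dim probe sets, the variance model, 1 probe set per gene, the arrays in the fit, each replicate left out in turn and a replicate block. Added after the data were seen were scaling on 18 hybridisation control probe sets, the pseudocount as planned, replicates 1 and 2 of control and severe only, and 81 gene families. A result past the threshold in neither setting was counted as kept, whatever its sign.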

Results

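Zebrafish embryos were injected at the 1-cell or 2-cell stage with 3 nl of a 0.3 mM antisense morpholino against prmt6 (MO), or with the same amount of a control morpholino. The prmt6 gene encodes protein arginine methyltransferase 6, which places methyl groups on histone arginines. At 6 hours post fertilization (hpf), as gastrulation begins, MO embryos had been sorted by shape into normal, mild and severe subtypes. Whole-embryo RNA was measured on Affymetrix zebrafish genome arrays. There were 3 control arrays, 3 severe arrays, 1 mild array and 1 normal array. The mild and normal subtypes therefore have no replicates of their own. The number of arrays limits the precision of each value. Each array held 15617 probe sets, and its median signal lay between log2 6.48 and 6.81.

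The array-wide profiles set severe and control embryos apart. On the first principal component the mild array lay on the side of the severe arrays and the normal array on that of the controls. The first principal component held 69.3% of the variance and the second 15.8%. On the second, controls 1 and 2 and severe 1 and 2 were negative. Control 3, severe 3, the mild array and the normal array were positive. Spearman correlations across probe sets, which are not independent replicates, were 0.993 between controls 1 and 2. Control 3 correlated at 0.971 with each of them. Severe arrays 1 and 2 correlated at 0.981, and severe array 3 at 0.959 and 0.966 with them. Severe array 3 correlated more closely with the mild array, at 0.983. The mild array correlated at 0.939 and 0.958 with severe arrays 1 and 2, and at 0.930 with the normal array. The labels named no batch that could be tested.

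**Figure D1:**
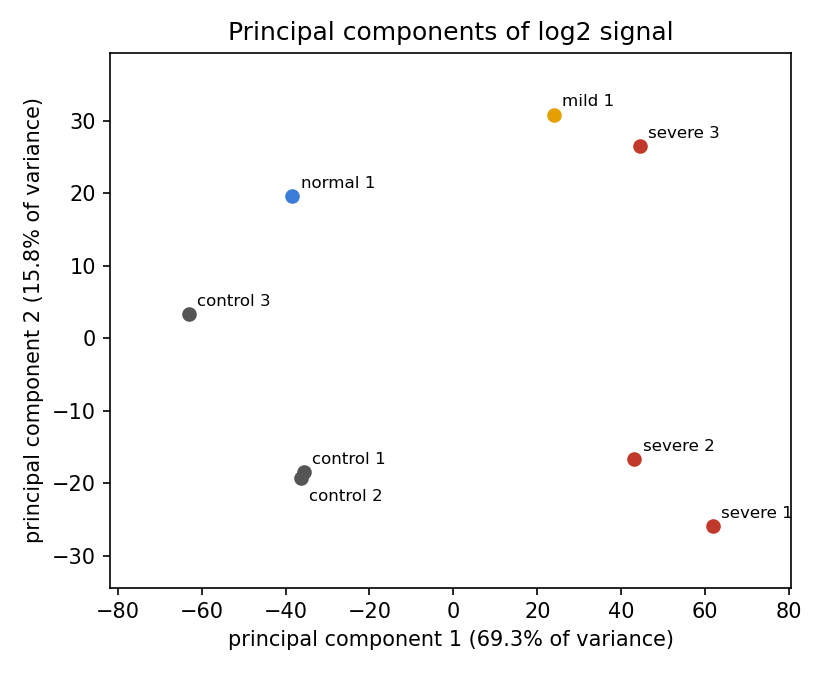
Each point is 1 array, placed by the first principal component (horizontal axis, 69.3% of variance) and the second (vertical axis, 15.8%) of log2 signal over the probe sets kept for testing. The 3 control arrays and the normal array lie at negative values of the first component, the severe and mild arrays at positive values, and severe 3 lies beside the mild array. Controls 1 and 2 and severe 1 and 2 are negative on the second component, and the other arrays are positive.

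The transcript of the injected target was higher, not lower, in every MO array. The prmt6 probe set read log2 9.70 ± 0.16 (SD, n = 3) in control embryos and 11.27 ± 0.16 (SD, n = 3) in severe embryos. That is a 2.96-fold rise (log2 1.57, SE 0.14, limma adjusted p = 0.000115), and all 3 severe arrays lay above all 3 controls. The mild array was 2.70-fold above the control mean (limma adjusted p = 0.00429), a call lost when arrays were scaled on their hybridisation controls (limma adjusted p = 0.0558). The normal array was 1.52 higher on the log2 scale and did not pass the threshold (limma adjusted p = 0.0517). A morpholino binds its target RNA and need not lower its level, so this transcript value checks neither the knockdown nor the labels. Among 8 measured members of the arginine methyltransferase list, 3 rose in severe embryos and 0 fell, also adjusted over the list alone. The other 2 were prmt7 (log2 0.53) and the methylosome subunit clns1a (log2 0.95). Both lost their call under several alternatives, and prmt5 differed by 0.36 without passing. The list as a set did not pass the set test (camera adjusted p = 0.683), and its median of 0.14 turned to -0.14 when arrays were scaled on their hybridisation controls.

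The comparison of severe with control embryos asks which transcripts accompany the strongest malformation. Rises included the stress genes hsp70.3 and gadd45aa and 25 of 40 maternal transcripts, and falls included 17 of 21 enveloping layer markers and 29 of 40 mesendoderm genes. Of 9301 probe sets tested, 3587 passed the threshold, 1951 higher and 1636 lower. Those with 1 gene symbol came from 1512 genes with a higher probe set and 1080 with a lower one. At 2-fold or more, 990 probe sets were higher and 1010 lower. When arrays were scaled on their hybridisation controls instead, 2377 probe sets passed, 474 higher and 1903 lower. That scaling moved the median difference of all probe sets from 0.11 to -0.17 on the log2 scale, so the balance of rises to falls rests on the scaling.

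The steepest rise was hsp70.3, a heat-inducible chaperone, from 5.62 ± 0.52 (SD, n = 3) to 9.76 ± 1.45 (SD, n = 3), or 17.6-fold (limma adjusted p = 0.0011). The next was gadd45aa, a growth-arrest and DNA-damage-inducible gene, from 6.62 ± 0.20 to 9.42 ± 0.48 (SD, n = 3 each). Its rise was 6.93-fold (log2 2.79, SE 0.27, limma adjusted p = 0.000149). Several of the other leading rises were transcripts best known from the egg or germ line. They were btg4 (log2 2.76), an adaptor for mRNA deadenylation, tbpl2 (2.75), the oocyte form of TATA-binding protein, the meiotic kinase mos (2.63) and the germ-cell RNA-binding protein dazl (2.51). On the control side, tbpl2 and hsd3b7 lay above the array background on 2 of 3 arrays, so their sizes are uncertain. The remaining leading rises were cdca9 (2.79), the eye-field homeobox gene rx3 (2.65), atf5a (2.64), hsd3b7 (2.58), the Polycomb gene bmi1a (2.55) and the deadenylase cnot7 (2.51). Each of these 12 genes was higher in all 3 severe arrays than in all 3 controls, as the naming rule required.

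The 12 leading falls included 3 keratin genes. The apolipoprotein gene apoc2 read 9.93 ± 0.86 (SD, n = 3) in controls and lay under the array background on all 3 severe arrays, so it was at least 28.4-fold lower (limma adjusted p = 2.93e-05). The zinc transporter gene slc39a5 was likewise at least 9.76-fold lower. The keratin genes krt97, krt17 and krt5 fell by 7.13, 6.17 and 6.04 on the log2 scale. Their severe arrays varied widely, with SDs of 3.57 for krt97 and 2.26 for krt5. The homeobox gene eve1, expressed in ventral and posterior mesoderm, fell from 10.53 ± 0.44 to 4.76 ± 0.88 (SD, n = 3 each; limma adjusted p = 5.86e-05). The neural and pluripotency gene sox2 fell by 5.26. Further falls were afp4 (-5.77), the actin-bundling gene lcp1 (-5.55), tmsb1 (-5.46), b3gnt5a (-5.35) and pttg1ipa (-5.03). Of the 10 genes with a fitted size here, krt97, krt5, afp4, lcp1, tmsb1 and b3gnt5a lay above the array background on 2 of 3 severe arrays. For krt17, eve1, sox2 and pttg1ipa it was 1 of 3, so the sizes and order of these falls are uncertain. All 12 of these genes were lower in every severe array than in every control, which the naming rule also required.

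**Figure D2:**
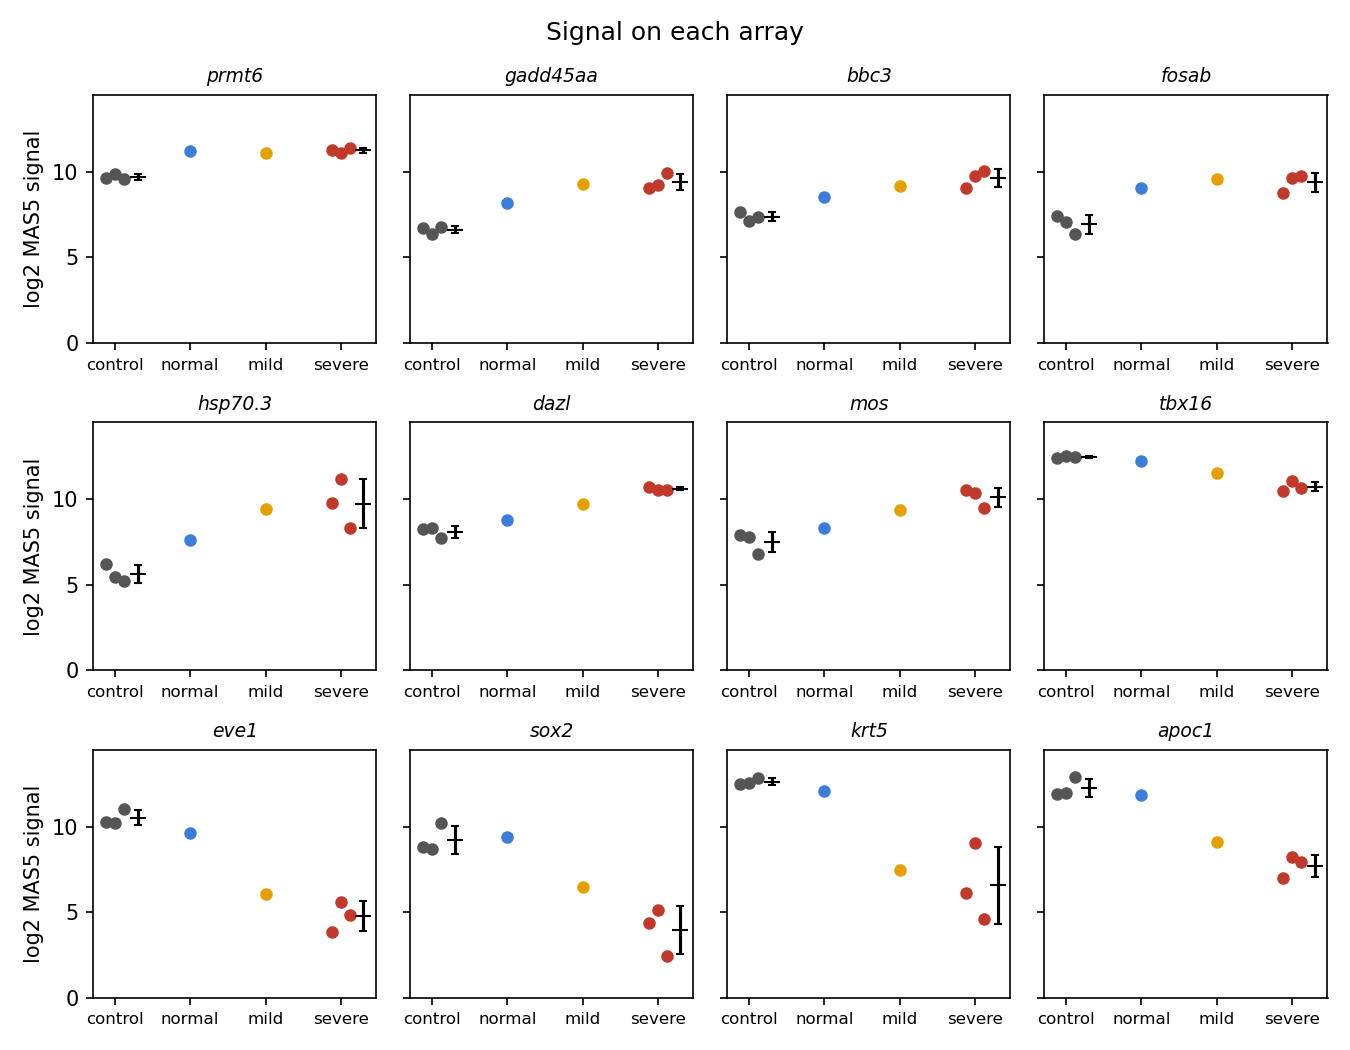
Log2 MAS5 signal (vertical axis) of 12 genes on each array, by group (horizontal axis). Each point is 1 array, and black marks give the mean and SD of the 3 control and the 3 severe arrays. Signal of prmt6 is 9.70 in controls and 11.27 in severe embryos, while eve1 reads 10.53 in controls and 4.76 in severe embryos.

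Maternally supplied transcripts were higher in severe embryos. Of 40 measured members, 25 rose and 2 fell, or 27 and 3 adjusted over the list alone, with a median of 0.77 (0.49 when scaled on hybridisation controls). Besides dazl, the germ-plasm gene dnd1 rose by 1.62 on the log2 scale, the oocyte claudin cldnd by 1.67 and the polyadenylation factor gene cpeb1b by 1.67. Germ-cell markers overlapped this list in 7 genes, and 5 of 9 rose and 1 fell (6 and 2 adjusted over the list alone). The linker histone h1m rose by 0.82 and nanos3 by 0.73, a call lost under scaling on hybridisation controls. The maternal list passed the set test with a preset correlation (camera adjusted p = 4.09e-05) but not when the correlation was estimated (adjusted p = 0.287). The germ-cell list did not pass (camera adjusted p = 0.0879) except when scaled on hybridisation controls or left unfiltered.

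Mesendoderm genes fell together. Of 40 measured genes of Nodal signalling and mesendoderm, 29 fell and 1 rose (31 and 2 adjusted over the list alone), and the median was -0.96. The T-box gene tbx16 fell from 12.50 ± 0.05 to 10.75 ± 0.28 (SD, n = 3 each; limma adjusted p = 9.5e-05; a second probe set, at -1.37, did not pass, limma adjusted p = 0.0873), the Notch ligand gene dlc fell by 3.87 (above background on 2 of 3 severe arrays) and lhx1a by 2.76. The list passed with the preset correlation (camera adjusted p = 6.63e-11) and not with an estimated correlation (adjusted p = 0.287). The dorsal organizer list, which shares 8 genes with it, had 12 of 26 members lower and 1 higher (13 and 1 adjusted over the list alone). There, the BMP antagonist chrd fell by 1.97, the Wnt antagonist dkk1b by 1.42 and the forkhead gene foxa2, above background on 2 of 3 severe arrays, by 2.63 (camera adjusted p = 0.00434, but adjusted p = 0.67 with an estimated correlation). Of 27 BMP and ventral genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -0.54. The ventral repressor ved fell by 3.03, the BMP target id3 by 3.07 and bambia by 2.36 (camera adjusted p = 4.09e-05, but adjusted p = 0.287 with an estimated correlation).

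The enveloping and yolk syncytial layers had the lowest medians of the lists, though no test compared lists with each other. In the enveloping layer, the outermost epithelium of the blastula, 17 of 21 markers fell and 1 rose (19 and 1 adjusted over the list alone), and the median was -2.38. The annexin gene anxa1a fell by 3.99, the calpain gene capn9 changed by -4.41 and the plakophilin gene pkp3a by -4.52 (above background on 1 of 3 severe arrays), while anxa1b was at least 12.7-fold lower. The yolk syncytial layer median was -1.81, and lay between -2.87 and -1.22 over the alternatives. There, 6 of 9 markers fell (6 adjusted over the list alone), among them apoc1 by 4.56 and gata6 by 2.87. The exception was mxtx2, a homeobox regulator of that layer, which rose by 1.71. Both lists passed with the preset correlation (camera adjusted p = 6.66e-11 and 0.00165) and neither with an estimated correlation (adjusted p = 0.287 and 0.523).

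Early zygotic genes went both ways, and most called movement genes fell. Among 37 early zygotic and pluripotency genes, 18 fell and 9 rose (19 and 10 adjusted over the list alone), and the clock gene her7 fell by 4.98, with 1 of 3 severe arrays above background. This list passed with the preset correlation (camera adjusted p = 0.00515), but not with an estimated correlation (adjusted p = 0.479) or when the dimmer 60% of probe sets were left out (camera adjusted p = 0.107). Of 41 genes of Wnt and planar polarity signalling, adhesion and cell movement, 12 fell and 1 rose (12 and 1 adjusted over the list alone). The GTPase genes rhoaa and rhoab fell by 2.68 and 2.71, the peptide gene apela by 3.68 and marcksa by 1.26 (camera adjusted p = 0.00441, but adjusted p = 0.287 with an estimated correlation). A second marcksa probe set read -0.19 without passing (limma adjusted p = 0.535). Neural plate genes went both ways, with 7 of 21 higher and 8 lower (8 and 8 adjusted over the list alone). This list shares 7 genes with the early zygotic list, which also shares 8 with the BMP list, so these results are not independent. Among neural plate genes sox19b rose by 1.63, while sox3 fell by 1.03 and zic2a by 1.41 (camera adjusted p = 0.81). Other sox3 probe sets read -1.91 (limma adjusted p = 0.000216) and -0.79, which did not pass (limma adjusted p = 0.0635).

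Stress and death genes changed one by one rather than as sets. In the p53 and DNA damage list, 2 of 21 rose and 3 fell (2 and 3 adjusted over the list alone). The pro-apoptotic gene bbc3 (puma) rose from 7.38 ± 0.26 to 9.62 ± 0.53 (SD, n = 3 each; limma adjusted p = 0.000454) and the repair gene ddb2 rose by 1.03. Both sesn3 and rps27l fell, by 1.69 and 1.81. Of 5 gadd45 family members, gadd45aa and gadd45bb (log2 0.83) rose and gadd45ba fell by 0.47, a call lost in several alternatives. The value for gadd45ga was -0.59 without passing in the main fit, though it passed in 8 of 19 alternatives, and adjusted over the list alone 2 rose and 2 fell. Of 22 apoptosis genes, 5 rose and 6 fell (7 and 7 adjusted over the list alone). In that list bokb rose by 2.08, and cycsb, diabloa and birc2 fell by 1.41, 2.22 and 1.55. Of 15 MAP kinase and AP-1 genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone). The immediate-early genes fosab and jun rose by 2.45 and 1.35, map3k4 rose by 0.76 and dusp6 fell by 1.13. Of 32 chaperone and unfolded-protein genes, 9 rose and 5 fell (9 and 6 adjusted over the list alone), with hsp90b1 and pdia4 up by 0.96 and 1.51 and hspb1 down (-1.53). None of these 5 lists passed the set test with the preset correlation (camera adjusted p from 0.81 to 0.954). Their medians lay between -0.12 and 0.25, and the 4 positive ones turned negative when arrays were scaled on hybridisation controls. The apoptosis median was above 0 while its set test pointed down, and the gadd45 median was below 0 while its mean (0.49) and set test pointed up. That scaling also ended the calls of ddb2 and map3k4. Second probe sets of jun (0.95), map3k4 (0.51) and gadd45ba (-0.70) did not pass.

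Ribosomal protein genes were modestly lower in severe embryos. Of 71 matched genes, 30 fell and 1 rose (32 and 1 adjusted over the list alone), and the median was -0.49. Examples were rpl7 (-1.25), rplp2 (-1.29), rps26l (-1.23) and rps27l (-1.81). The riser, rps6kal (1.31), is a kinase gene caught by its symbol, not a ribosomal protein, and was singled out after its value was seen. The list passed with the preset correlation (camera adjusted p = 1.59e-09) and not with an estimated correlation (adjusted p = 0.67), which was 0.88 between members. The per-array medians were -0.85, -0.57 and -0.16 in severe embryos and -0.15, -0.22 and 0.38 in controls, so severe 3 overlapped controls 1 and 2.

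**Figure D3:**
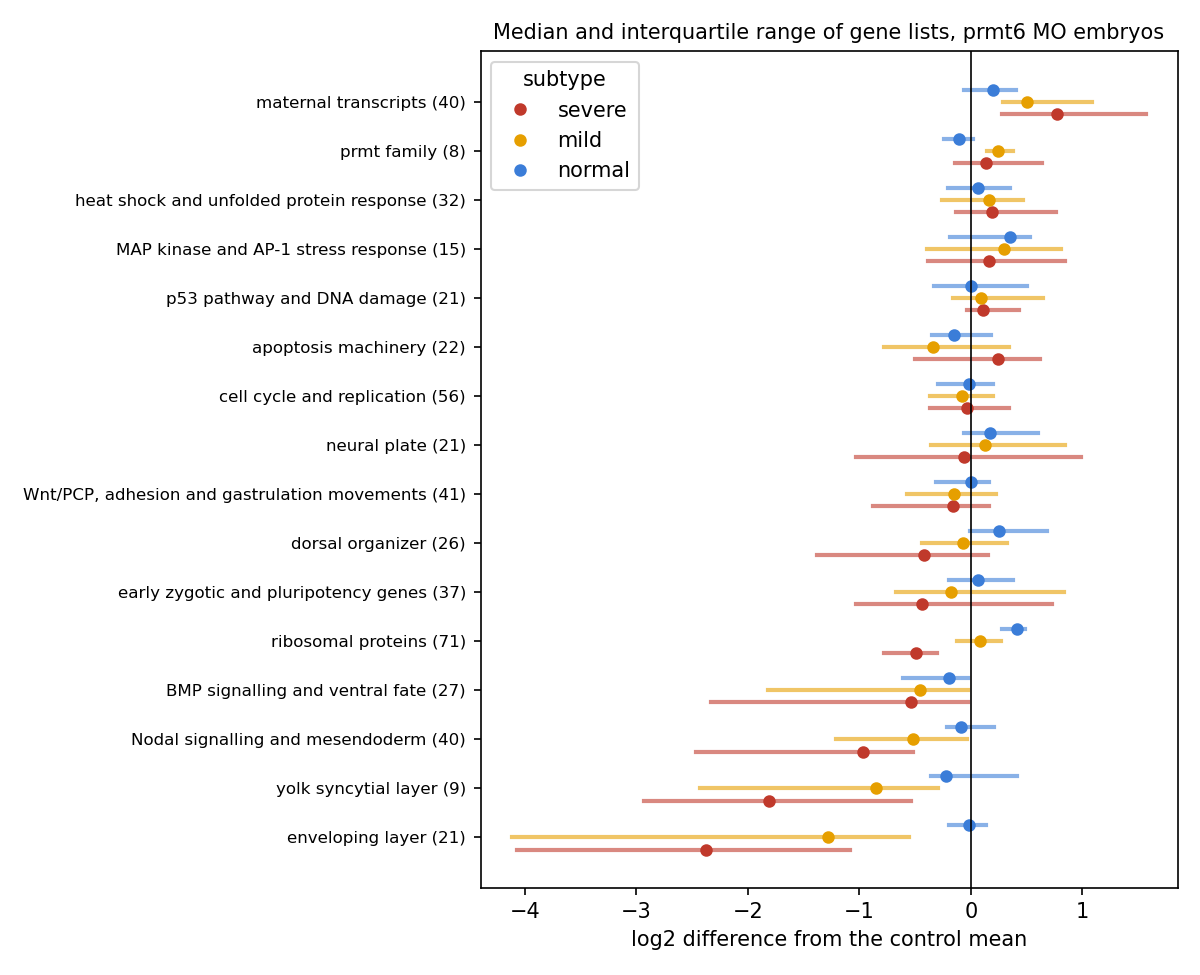
Median (points) and interquartile range (lines) of log2 differences from the control mean (horizontal axis) for 16 gene lists (vertical axis, number of genes in brackets), in severe (mean of 3 arrays), mild and normal (1 array each) MO embryos. The enveloping layer median is -2.38 in severe, -1.28 in mild and -0.02 in normal embryos. Small medians on either side of 0 can change sign with the scaling.

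The comparison of mild with control embryos asks whether a weaker malformation shows like changes. The leading rises on the mild array were hsp70.3 (log2 3.80), gadd45aa (2.68), arhgap11a (2.64), the immediate-early gene fosab (2.62) and igfbp1a (2.46; above background on 2 of 3 controls). The leading falls were krt5 (-5.18) and 4 genes under the array background there. Those were krt17 (at least 21.3-fold lower), the secreted BMP regulator szl (at least 31.1-fold), anxa1c (at least 6.35-fold) and pttg1ipa (at least 24.1-fold). In all, 1253 of 9301 probe sets passed in limma, 436 higher and 817 lower. Median centring gave 718 higher and 575 lower, and scaling on hybridisation controls 30 and 967. Those scalings moved the median of all probe sets from 0.03 to 0.24 and -0.42 on the log2 scale. The fit assumed that the lone mild array varies like the replicated groups. The count was 670 without control 1, 615 without control 2 and 1893 without severe 3, and it was 3037 with replicates 1 and 2 of both groups only. The calls for hsp70.3, krt5 and igfbp1a were among those lost in some alternatives.

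The 4 lists past the set test on the mild array had medians in the severe direction. Maternal transcripts had 12 of 40 members higher and 0 lower (14 and 1 adjusted over the list alone; median 0.50). Mesendoderm genes had 10 of 40 lower and 2 higher (13 and 2 adjusted over the list alone; median -0.52). BMP and ventral genes had 9 of 27 lower and 1 higher (11 and 1 adjusted over the list alone; median -0.45). The enveloping layer had 10 of 21 lower (15 lower and 1 higher adjusted over the list alone; median -1.28). They passed with the preset correlation (camera adjusted p = 2.13e-05, 0.000613, 0.000884 and 4.7e-08) and none with an estimated correlation (adjusted p = 0.471 for each). When scaled on hybridisation controls, the maternal median was only 0.0546, the mesendoderm median -0.97 and the BMP median -0.90, all still past the set test. Median centring gave -0.31 for mesendoderm and -0.24 for BMP. Medians opposite in sign to severe embryos, in lists that passed in neither comparison, were apoptosis (-0.34), gadd45 (0.32) and neural plate (0.13). The severe signs turned with the filter on dim probe sets. With no filter the severe gadd45 median was 0.36. With the filter at the 60th percentile the severe apoptosis median was -0.04 and the severe neural plate median 0.19. The yolk syncytial layer had 3 of 9 lower and 1 higher (3 and 1 adjusted over the list alone; median -0.85). It did not pass in the main fit (camera adjusted p = 0.0527; adjusted p = 0.635 with an estimated correlation) but passed in 11 of 18 alternatives, and its median ranged from -2.43 with the stricter filter to -0.63 with median centring. Among single genes on the mild array, bbc3 rose by 1.82, rx3 by 2.36 and the yolk syncytial layer gene mxtx2 by 2.03. Ribosomal protein genes had a median of 0.09 with 1 of 71 lower (0 adjusted over the list alone; camera adjusted p = 0.876). The set test compares a list with the other genes, so the sign of a median alone gives no direction. Scaling on hybridisation controls moved the median of all probe sets to -0.42. The ribosomal list passed in 2 of 18 alternatives, with medians of opposite sign. Its median was -0.36 when scaled on hybridisation controls (camera adjusted p = 0.00964) and 0.26 with control and severe replicates 1 and 2 only (camera adjusted p = 0.00216).

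Severe and mild calls overlapped. Both comparisons called 395 probe sets higher and 745 lower, and 0 in opposite directions. Independent lists would share 91.5 and 143.7. The correlation of the log2 differences across probe sets, which are not independent replicates, was 0.852, against 0.356 in 50 simulations of unchanged groups set against the same controls. The covariance was 0.723 against a simulated 0.0431, and 78.3% of probe sets had the same sign against 61.6%. The simulated groups lack the real changes, which widen the differences, so the covariance is the closer comparison. Noise in the shared controls is part of the simulated 0.0431, so it does not account for the excess over that value. A departure common to all 3 controls is not simulated and may add to the excess. The 3 controls cannot be split into parts of 2 arrays each to check this. On a scale from the control level (0) to the severe level (1), measured on probe sets chosen without the arrays compared, the mild array lay at 0.808 ± 0.0808 (SD over 3 held-out choices).

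Severe and mild embryos were compared directly as well. Limma called 0 of 9301 probe sets, with 948 at an unadjusted p under 0.05 and a smallest adjusted p of 0.481. Without severe 3, the severe array closest to the mild one, 11 passed. With replicates 1 and 2 of control and severe only, chosen after the data were seen, 2640 passed. The missing calls therefore do not show that the subtypes are alike. Nor can the calls with replicates 1 and 2 only be assigned to the subtype. The mild array lay apart from those arrays on the second principal component.

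The comparison of normal-looking MO embryos with controls asks how the prmt6 and control morpholinos differ without visible malformation. Limma called 4 of 9301 probe sets, all lower. The endoplasmic reticulum stress gene serp1 fell by 1.80 on the log2 scale and was also lower in severe (-1.38) and mild (-1.66) embryos. The ubap2b signal fell by 1.51. The other 2 were eif5b (-2.38), a translation initiation factor, and gemin5 (at least 2.35-fold lower, under background on the normal array), both named after their values were seen. Each was called on 1 of several probe sets. A second eif5b probe set read -0.36 (limma adjusted p = 0.711), and the brightest gemin5 probe set read -0.62 (limma adjusted p = 0.714). At an unadjusted p under 0.05 there were 865 probe sets. The count was 0 without control 1, control 2, control 3 or severe 2, it was 14 without severe 3, and it was 1094 with replicates 1 and 2 only.

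Among named genes on the normal array, gadd45aa was 1.54 above the control mean (limma adjusted p = 0.336), mxtx2 1.58, bbc3 1.17 and jun 1.11, each above all 3 controls and none past the threshold. Eve1 was -0.90 and krt5 -0.53. Ribosomal protein genes had a median of 0.42 with 0 of 71 called (camera adjusted p = 2.09e-09, but adjusted p = 0.677 with an estimated correlation). Maternal (0.20), MAP kinase and AP-1 (0.35), dorsal organizer (0.25) and germ-cell (0.28) medians also passed with the preset correlation only (camera adjusted p from 0.016 to 0.0447, and adjusted p = 0.677 with an estimated correlation). Of 18 alternatives, 9 ended the MAP kinase call, 9 the germ-cell call, 6 the organizer call and 5 the maternal call with its sign kept. The BMP and ventral list, with a median of -0.19, did not pass in the main fit (camera adjusted p = 0.0777) but passed in 8 of 18 alternatives. Adjusted over the list alone, 3 MAP kinase and AP-1 genes rose and 1 fell, 1 maternal and 1 germ-cell gene rose, and 0 organizer or ribosomal genes changed. The maternal, organizer and germ-cell medians turned negative under scaling on hybridisation controls, which moved the median of all probe sets from -0.03 to -0.37. Under it the MAP kinase and AP-1 median was 0.00852 and the ribosomal median 0.0765. That scaling shifts each list alike, so the sizes of these 5 medians rest on it. The ribosomal median stayed above 0 in every alternative, between 0.0765 and 0.58. Measured from the control mean, control 3 alone had a ribosomal median of 0.38, close to the normal array, against -0.15 and -0.22 on controls 1 and 2. The normal array lay at 0.168 ± 0.0787 (SD over 3 held-out choices) on the scale from control to severe. The log2 differences of severe and normal embryos had a covariance of 0.117, against 0.0428 in simulations of unchanged groups. They correlated at 0.252 against 0.353, but changes in severe embryos widen the real differences, so these correlations cannot be compared directly.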

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

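The tests of the pattern in this part were chosen after the arrays had been compared. The replicated groups hold 3 arrays each, too few for a test of outlying arrays.

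Spike-in controls, RNAs added by the array protocol and left out of the main comparisons, read higher on several MO arrays than on any control array. Hybridisation controls averaged log2 10.78 ± 0.10 (SD, n = 3) in controls, with a highest value of 10.89. They read 10.98 on severe 2, 11.39 on severe 3, 11.13 on the normal array and 11.23 on the mild array. Poly-A controls averaged 7.39 ± 0.13 (SD, n = 3) in controls and read 7.58 on severe 1, 8.27 on severe 3 and 7.83 on the mild array, against a highest control value of 7.51.

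Severe 3 lay closer to the mild array than to severe 1 and 2. The departure of severe 3 from severe 1 and 2 correlated at 0.377 across probe sets with the departure of the normal array from controls 1 and 2, so a batch, clutch or stage shared by these arrays may account for part of the pattern. The departure of control 3 from controls 1 and 2 correlated at 0.338 with that of severe 3. The departure of the mild array from severe 1 and 2 correlated at 0.434 with that of the normal array. A weaker response of severe 3 stays open: severe 3 minus severe 1 correlated at 0.280 with control 1 minus severe 2. The cut-offs for reading these correlations were set after the data were seen. The values of 0.377 and 0.280 therefore do not rank the explanations. The labels name no batch, so none was fitted as a block.

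Several gene lists differed between severe and mild embryos in the test of that difference with the preset correlation, and in none with an estimated correlation (adjusted p = 0.478 to 0.484). The severe minus mild median was -0.32 for early zygotic and pluripotency genes. It was -0.57 for Nodal signalling and mesendoderm. It was -0.61 for the dorsal organizer. It was -0.11 for Wnt, polarity and movement genes. Ribosomal protein genes also differed by -0.61. The enveloping layer differed by -0.60 and the yolk syncytial layer by -0.70. Against the control mean, organizer medians were -0.58, -0.48 and -0.23 on severe 1, 2 and 3 and -0.07 on the mild array. Ribosomal medians were -0.85, -0.57 and -0.16 against 0.09, and yolk syncytial layer medians -2.28, -2.12 and -1.04 against -0.85. In these 3 lists most of the difference therefore came from severe 1 and 2, the arrays that severe 3 stands apart from. Mesendoderm medians ran likewise, at -1.44, -1.13 and -0.83 against -0.52. The enveloping layer did not, at -2.77, -1.90 and -2.62 against -1.28. Nor did early zygotic genes (-0.43, -0.25 and -0.31 against -0.18) or Wnt and movement genes (-0.13, -0.19 and -0.15 against -0.15).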

How the results depend on the processing

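Scaling on hybridisation controls, replicates 1 and 2 only and the planned pseudocount were chosen after the data were seen. The severe against control count lay between 2377 (scaling on hybridisation controls) and 4485 (replicates 1 and 2 only). Of the 3587 probe sets, 3446 also passed after quantile normalization and 2038 with scaling on hybridisation controls. Leaving out 1 array gave 2739 to 4187. The mild count was 615 to 1893 with 1 array left out and 3037 with replicates 1 and 2 only. The normal count of 4 was 1 after quantile normalization, 0 with scaling on hybridisation controls, 2 with no filter, 1 with trend = FALSE, 7 with only the arrays compared, 0 to 14 with 1 array left out and 1094 with replicates 1 and 2 only. Severe against mild was 0 to 11 with 1 array left out and 2640 with replicates 1 and 2 only. Controls 1 and 2 and severe 1 and 2 are close pairs, so that setting has a smaller spread and fewer arrays. On the second principal component those arrays lay between -25.9 and -16.6. The mild array lay at 30.9 and the normal array at 19.6. The mild and normal counts in that setting may therefore follow this axis, which cannot be told apart from the subtype there. For the other changes the cause was not tested. Positions ranged from 0.781 to 0.836 (mild) and 0.142 to 0.221 (normal).

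Scaling on hybridisation controls reversed list medians to -0.13 (gadd45), -0.36 (ribosomal) and -0.11 (germ cells) in mild, and to -0.11 (gadd45), -0.14 (maternal), -0.0854 (organizer) and -0.0574 (germ cells) in normal embryos. It subtracts 1 value per array, which shifts each list alike. Medians called in neither setting also turned negative under it, for 5 lists in severe, 6 in mild and 5 in normal embryos. In mild embryos these were arginine methyltransferases (-0.21), p53 (-0.36), MAP kinase (-0.15), chaperones (-0.28), innate immunity (-0.34) and neural plate (-0.32). Over 1856 values of 99 named genes, 1811 stayed on their side of the threshold, 34 lost a call, 11 gained one and 0 called values reversed. Among the 1811, 11 values of 3 genes (ckma, gata2a and tnnt3a), called in neither setting, changed sign.

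The values do not decide whether replicate numbers pair the arrays, as each deviation is taken from the mean of few arrays. Same-numbered control and severe arrays deviated with correlations of 0.337, -0.072 and 0.338. Control 1 correlated best with severe 1, and control 3 with severe 3. Control 2 correlated best with severe 1 (0.385), not with severe 2. With a replicate block 4413 probe sets passed, 3583 of them also in the fit without it. Among named genes it added calls for prmt5 (limma adjusted p = 0.0446), gadd45ga (0.0239) and ubap2b (0.0392) in severe embryos and ended none.

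Signal near background limits dim genes: folds to a group under log2 5.10 on every array are lower bounds, and sizes of falls with only some arrays above it are uncertain.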

Other observations

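The gene lists were fixed before the data were examined. The tests of explanations were chosen after results were seen, except the one on mean-matched random lists.

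Cell-cycle, immune and late tissue genes complete the lists. Of 56 cell cycle and replication genes, 8 rose and 9 fell in severe embryos (7 and 9 adjusted over the list alone; camera adjusted p = 0.374). The cyclin gene ccnb3 fell by 2.11, and the replication helicase genes mcm3 and mcm5 were at -1.56 and -0.91, while ccnb2 rose by 0.97. Of 9 innate immune genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.954). There b2m (-2.02) and nfkbiaa (-1.37) fell, and irf5 and nfkb2 rose by 1.33 and 0.79, calls lost in several alternatives. Only 1 of 42 hox genes on the array was bright enough to test, and hoxc11a differed by 0.56 without passing, except in 1 of 18 alternatives. Of 2 blood genes, drl fell by 1.81, and gata2a read 0.01. Of 4 muscle genes, the actin gene actc1a rose by 2.27, while actc1b, tnnt3a and ckma differed by -0.60, -0.13 and -0.04 without passing. Neither list passed the set test (camera adjusted p = 0.208 and 0.954). The muscle median was -0.08 while its mean (0.38) and set test pointed up.

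In a scan of 81 families by symbol stem, made after the data were seen, the symbol stems rpl and rps passed with the preset correlation (camera adjusted p = 8.58e-06 and 0.00459) and no other did. Besides ribosomal proteins, the rps stem caught the kinase genes rps6ka1, rps6ka3a, rps6kal and rps6kb1b and the binding-protein gene rps19bp1. Closest were ndufa, of the NADH dehydrogenase complex, and the splicing factor family srsf, each with camera adjusted p = 0.0538. Of 12 ndufa genes, 7 fell and 1 rose (median -0.69), and of 13 srsf genes 6 fell and 0 rose (median -0.27). With an estimated correlation each of these 4 families had adjusted p = 0.916.

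The severe against control count was set against other splits of the same 6 arrays. The real split gave 3587 probe sets and the highest of the others 0, so 1 of 10 splits gave as many. Each other split mixed control and severe arrays in both of its parts. The difference between them then entered the spread, which made calls there unlikely from the start. With 10 splits the share cannot go under 1 in 10, and so not under 0.05. The count of 0 therefore does not decide the question.

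Maternal transcripts were higher while mesendoderm genes were lower in severe embryos, a gap of 1.74 between the list medians. A shift of whole arrays cannot move this gap. Against signal-dependent scaling as the whole cause, the smallest gap over quantile normalization and the pseudocounts was 1.60. Against severe 3, with the highest spike-in controls, the gap without it was 2.21. Loss of the enveloping layer alone would raise markers of every other cell type, yet the mesendoderm median was -0.96 with an interquartile range of -2.46 to -0.52. As a hypothesis, severe embryos may be delayed in development, and this cannot be told apart from other changes here: the neural plate median was -0.0614 with members going both ways, and no staged reference was used here.

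Ribosomal protein genes were lower in severe embryos, with a median of -0.49. Against compression of bright probe sets, random lists matched on mean signal had a median of only -0.08. Of 10000 such lists, 0% had a median as low. They draw unrelated genes, while ribosomal members correlated at an estimated 0.88, so that share overstates the evidence. Against the difference between replicates 3 and replicates 1 and 2, the median was -0.51 with control and severe replicates 1 and 2 only. Against scaling, the value nearest to 0 over the scalings was -0.37 and the lowest -0.77. A change in severe embryos is consistent with these values as a hypothesis, though the list did not pass with an estimated correlation and a shared stage or clutch difference stays open.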
